A study of Mus musculus with 6 samples.

How the data were processed

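The series holds 6 samples of RAW264.7 cells, 3 controls in medium and 3 with AEPS at 50 µg/ml, all taken at 4 h. Per the labels' protocols, total RNA was copied into Cy3-labelled cRNA. Per the file headers, the arrays were read with Agilent Feature Extraction 10.7.1.1. Each deposited scanner file gives spot intensity values: a processed signal after background subtraction and detrending within the array, the mean pixel signal and the local background, per the file headers, with flags for each spot. No normalization between arrays had been applied to them. The authors' deposited value table holds 1 column per sample on a scale close to log2 of the processed signal. Its sorted columns differed by at most 0.01 and each had a median of 4.71, as quantile normalized columns do; no gene centring was seen, and the exact log offset is not given in the sources used here.

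The files and the table were compared before use. Files of replicates 1 and 2 were identical within each group, and their values entered as 1 replicate. The file given for replicate 3 ranked probes as the table's replicate 2 column did in both groups (Spearman 0.999999), and the table's replicate 3 columns matched no scanner file. The scanner fit therefore rests on 2 distinct arrays per group and the table on 3.

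Control spots were left out, spots flagged as non-uniform or population outliers were set to missing, and spots of 1 probe were averaged. Values were log2 of the processed signal minus each array's 75th percentile over non-control spots, which was 401, 287, 575 and 488 in signal units on the first and second control and AEPS arrays. A probe was tested if well above background on every array of at least 1 group, which held for 30374 probes. A gene below background in 1 group was thus tested only if bright in the other, which largely fixes its direction. Of 55681 probes, 26582 were named through an accession in the RefSeq table of assembly GRCm38.p6, 4222 by the scanner annotation alone, and 24877 had no gene name. The array's genome build is not given in the sources used here, so no coordinates are printed. A gene with several tested probes was represented by the brightest. Of 3710 such genes, 53 had probes moving more than 0.5 on the log2 scale in opposite directions.

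Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over 25881 features, named genes and unnamed probes together, at an adjusted p of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 29 lists, and again with an estimated correlation and with fry. With 2 arrays per group an estimated correlation leaves camera little power. A list failing with it is therefore not shown to be unchanged. Adjusted p-values of single genes are from limma throughout. A gene not well above background on any array of a group has only a bound there. Its fold is given as at least N, from the brighter group's mean against, per array, the higher of its own signal and the lowest signal among probes well above background.

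The design, tests, 29 lists, the rule for naming genes and all alternatives but those named as added were fixed before the data were examined. The rule takes the 10 largest rises and falls among genes past the threshold and measured on all arrays, the 5 largest from or to background, up to 4 members per list that passed and the brightest that did not, and 21 readouts whatever their value. A gene that it takes is not reported here. Members outside it are named where 1 or 2 of a list are singled out, namely Klf4, Card9, Plau, Mmp19 and Mcm5, chosen after their values were seen, as were the single histone genes, which are in no list. The lists include 4 of other cell types, as background checks in a clonal line.

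Replicate numbers were checked for pairing. In the authors' table the deviations of same-numbered samples from their group means correlated at 0.58, 0.38 and 0.42 across genes, against -0.50 to 0.24 for other pairs, all 3 above the bound of 0.1. On the scanner arrays the slides gave 0.62, and each slide holds 1 replicate of each group, so the slide served as the replicate block and as the scan batch. The main fit was planned without covariates and ignores this pairing. Results with the block are given as an alternative. With 1 array of each group per slide, the block leaves a log2 change as it is where no spot is missing.

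The calculations were tested on simulated data for 25850 genes. With 2 against 2 arrays and 200 changed genes none was recovered, and with 2000 changed genes 43.7% of 2-fold and 73.7% of 4-fold changes were recovered with 67 false calls. With 3 against 3 arrays and 200 changed genes 51% and 78% were recovered with 8 false calls. A shifted list was called and unchanged lists were not in each simulation. Noise was drawn independently for each gene and camera was run with the preset correlation only. The simulations therefore do not show how often unchanged lists of correlated genes would be called. Alternatives covered the block, each array left out, background, scaling, the filter on dim probes, flags, probes per gene, the variance model, the test and its threshold, and counting the identical files separately.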

Results

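RAW264.7 cells, an established mouse macrophage line, were exposed to AEPS, a root polysaccharide of the plant Actinidia eriantha, at 50 µg/ml for 4 h, or kept in medium alone. Total RNA of 3 samples per group was labelled with Cy3 and hybridised to 1-colour Agilent arrays carrying mouse mRNA and long intergenic RNA probes. The scanner files of replicates 1 and 2 held identical values in both groups, so each such pair was counted as 1 sample, which left 4 distinct arrays, 2 per group. They lay on 2 slides, each with 1 control and 1 AEPS array. Of 59305 non-control spots, 58.7% and 55.4% were well above background on the control arrays and 56.7% and 55.4% on the AEPS arrays. The number of arrays limits the precision of every value below. The labels do not say that the samples came from separate cultures, so p-values measure the spread among these samples, which may be technical.

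The comparison asked which transcripts differed after 4 h of AEPS. By limma, 19 of 22 measured cytokine genes, 13 of 19 chemokine genes, 18 of 26 NF-kB genes and 26 of 39 interferon-stimulated genes rose and none of them fell. The lists named 25, 25, 26 and 42 genes. Those not measured were missing from the array or not above background on every array of either group. Of the measured genes 9, 2, 0 and 1 were below background in 1 group, so the filter largely fixed their direction. Each of these lists passed camera with a preset correlation but not with an estimated correlation (adjusted p = 0.587 for each). With only probes above background on every array, each still passed at the preset. The estimates were 0.32, 0.18, 0.37 and 0.35 against the preset 0.01, so camera's preset p-values may be far too small. Each list also passed fry, with adjusted p = 0.00851, 0.00678, 0.0173 and 0.0152. An estimate from 2 distinct arrays per group leaves camera little power, so this failure decides little. Il1b, which encodes the inflammatory cytokine interleukin-1 beta, rose by 8.34 ± 0.17 on the log2 scale, and the neutrophil-attracting chemokine Cxcl2 by 7.98 ± 0.15 (limma's moderated SE, 2 distinct arrays per group, as for all log2 changes below). A moderated SE draws each gene's spread towards that of all genes, so it is not the spread of that gene alone. Lif and Cish, not well above background on either control array, were at least 191-fold and 190-fold higher. Falls were smaller: among genes measured on all arrays the steepest named by the rule were C130050O18Rik at -3.80 ± 0.15, Ier5l at -3.31 ± 0.16 and Myadml2 at -3.01 ± 0.14.

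By limma with Benjamini-Hochberg adjustment, 1285 of 14752 named genes passed an adjusted p of 0.05, 775 higher and 510 lower with AEPS. A change of at least 2-fold was met by 1075 of them, 660 higher and 415 lower. Among 11129 probes without a gene name, 554 passed, 305 higher and 249 lower. All 1285 genes changed in the same direction on both slides. Their selection on these same arrays largely fixes this, so it is no separate check. With the slide as a replicate block 4964 genes passed, 2442 higher and 2522 lower, and 1280 of the 1285 were among them. In the authors' deposited value table, which holds 3 distinct arrays per group, 6082 genes passed, 3178 higher and 2904 lower. Of the 1285 genes, 1263 were among them, all in the same direction. As 2 of those 3 arrays per group are the arrays of the scanner fit, much of this overlap is built in. Leaving out any 1 array left a group with only 1, so fewer genes passed whichever array was dropped. Of 101 log2 changes of named genes past the threshold, 0 grew or shrank by over 1.5 times in any such run. The remaining arrays had also served to choose these genes. The split between directions was 4260 higher and 136 lower when arrays were scaled to their spike-in probes, and 1470 higher and 1461 lower after normexp background correction. The median log2 change of all named genes was -0.10 by the 75th percentile and 0.56 by spike-ins, and falls are relative to the first of these. Spike-in scaling shifts all genes of an array alike, here upward with AEPS, so the 775 rises had to stay above 0. All 510 falls kept values below 0, but only 906 of the 1285 genes still passed with that scaling.

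**Figure D1:**
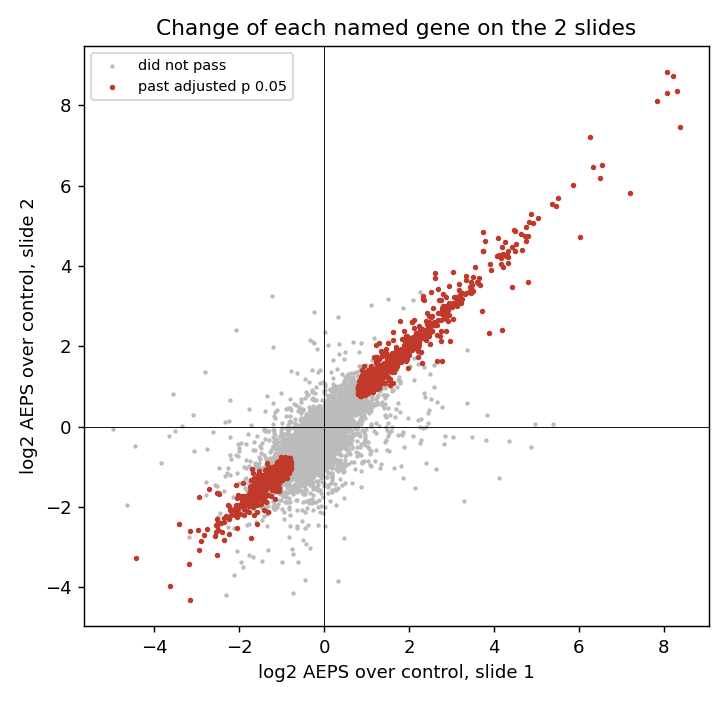
Log2 ratio of AEPS over control for each named gene on slide 1 (x axis) and slide 2 (y axis), with genes past an adjusted p of 0.05 in red and others in grey. The 1285 red genes lie in the upper right and lower left quadrants, which their selection on these same arrays largely fixes. The correlation across all named genes, which are not independent replicates, was 0.869.

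Arrays of a group resembled each other more than arrays of different groups. Over tested named genes, Pearson's r was 0.993 between the control arrays and 0.992 between the AEPS arrays, against 0.966 to 0.974 between groups.

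The usual readouts of macrophage activation mostly rose. Tnf rose by 3.60 ± 0.18 (adjusted p = 0.0104), Ptgs2, the inducible prostaglandin synthase, by 4.26 ± 0.17 (adjusted p = 0.00894), and Nos2, the inducible nitric oxide synthase, by 1.67 ± 0.14 (adjusted p = 0.0226). Il6 was not well above background on the control arrays and was at least 7.01-fold higher with AEPS (adjusted p = 0.00894). The anti-inflammatory cytokine gene Il10 rose by 2.27 ± 0.17 and Ifnb1, encoding interferon beta, by 4.96 ± 0.16. Ccl2, Ccl5 and Cxcl10 rose by 3.01, 6.53 and 3.38, Cd40 by 3.21, and the receptor gene Tlr2 by 1.38. Nfkbia, which encodes an inhibitor of NF-kB, rose by 1.81. The other readouts in the list of pattern recognition receptors, Tlr4, Cd14 and Clec7a, did not pass. Tlr4 had -0.75 ± 0.15 (adjusted p = 0.0647, and 0.0389 with the replicate block). Cd14 had 0.18 ± 0.16 (adjusted p = 0.488, but 0.39 with an adjusted p of 0.0203 in the authors' table). Clec7a, the beta-glucan receptor dectin-1, had 0.58 ± 0.17 (adjusted p = 0.109, and 0.0371 with the block). Actb had -0.55 and Gapdh -0.49, neither past the test (adjusted p = 0.196 and 0.116), and both turned above 0 with spike-in scaling. Arg1 and Cd86 were not well above background on every array of either group and were not tested.

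**Figure D2:**
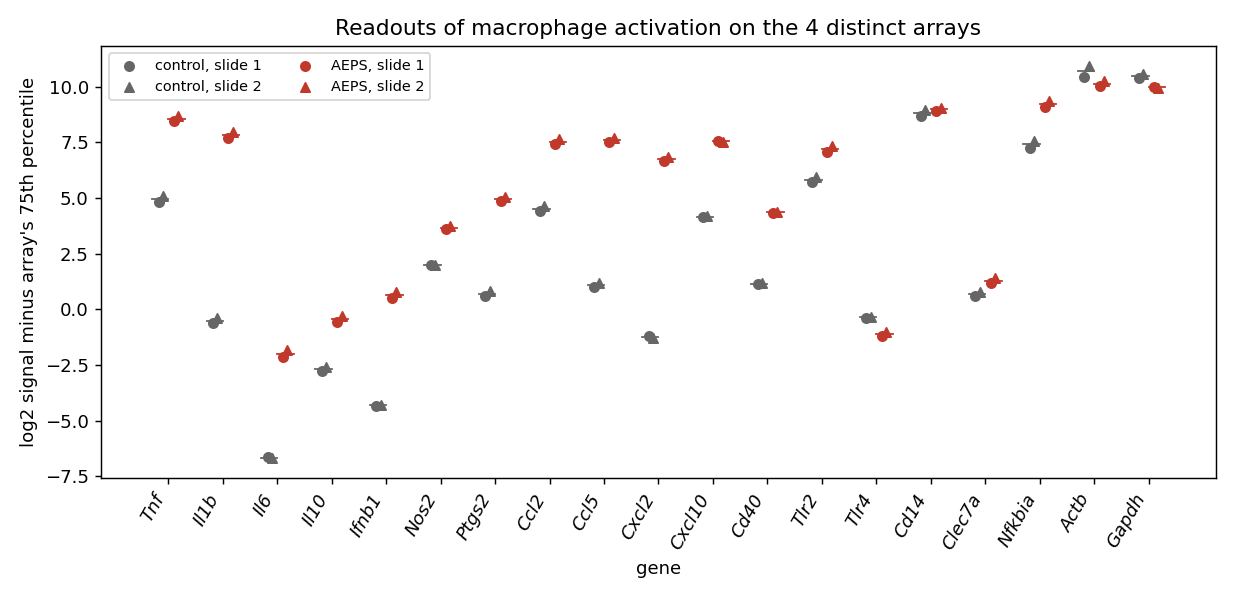
Normalized log2 signal (y axis, relative to each array's 75th percentile) of 19 readout genes (x axis) on the 4 distinct arrays, controls in grey and AEPS in red, slide 1 as circles and slide 2 as triangles, with short lines at the group means. Il1b lies at a mean of -0.52 in controls and 7.82 with AEPS, while Cd14 lies at 8.80 and 8.98.

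Cytokine genes formed the list with the largest shift. Of 22 measured members 19 rose and none fell (22 and 0 adjusted over the list alone), with a median log2 change of 3.53, or 3.14 with the 9 members below background in controls set to their bounds. The medians on slides 1 and 2 were 3.54 and 3.52; slide medians of other lists follow in this order. Camera gave an adjusted p of 4.32e-24 with its preset correlation and an adjusted p = 0.587 with an estimated correlation. Il1a was at least 71.7-fold higher, and Csf3, encoding granulocyte colony-stimulating factor and above background on 1 of 2 control arrays, rose by 8.45 ± 0.27. Ebi3 had 0.49 ± 0.13 (adjusted p = 0.102, and 0.0424 with the block). Of 19 measured chemokine genes 13 rose and none fell (15 and 1 over the list alone), with a median of 2.78 and slide medians of 2.93 and 2.63 (camera adjusted p = 4.13e-14, and adjusted p = 0.587 with an estimated correlation). Ccl22 and Cxcl3 were at least 59.9-fold and 17.1-fold higher. Cxcl11 had -0.42 ± 0.16 and did not pass (adjusted p = 0.177).

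Genes of the NF-kB pathway and its feedback rose in 18 of 26 cases and fell in none (21 and 0 adjusted over the list alone). Their median was 1.58, with slide medians of 1.5 and 1.73 (camera adjusted p = 1.48e-15, and adjusted p = 0.587 with an estimated correlation). Nfkbiz rose by 4.06, the feedback inhibitor Tnfaip3 by 3.31, the endoribonuclease gene Zc3h12a by 3.29 and Tnfaip2 by 2.99. Among immediate-early and MAPK feedback genes 13 of 30 rose and Klf4 fell (14 and 4 over the list alone, 15 and 4 with the replicate block), with a median of 0.38 and slide medians of 0.40 each (camera adjusted p = 9.48e-05, and adjusted p = 0.973 with an estimated correlation). Gadd45a rose by 4.11, Ier3 by 3.59, and Maff and Myc by 2.86 each. Fos had -0.44 ± 0.15 (adjusted p = 0.147, and 0.0463 with the block).

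Interferon-stimulated genes rose in 26 of 39 cases and fell in none (31 and 2 adjusted over the list alone). The median was 1.37, with 1.38 and 1.44 on the slides (camera adjusted p = 8.15e-20, and adjusted p = 0.587 with an estimated correlation). Ifit1 rose by 4.53 ± 0.14, the ubiquitin-like modifier Isg15 by 4.36 ± 0.16, the RNA sensor Ifih1 by 3.68 and Rsad2 by 3.54. Gm9706, a pseudogene in the RefSeq table and among the 10 largest rises at 4.69, is uncertain, since its probe was not compared with related transcripts. Oas1a had -0.14 and did not pass (adjusted p = 0.536). In the SOCS and JAK-STAT list 7 of 20 rose and none fell (11 and 0 over the list alone, 12 and 1 with the block), with a median of 0.72 and slide medians of 0.68 and 0.76 (camera adjusted p = 2.53e-07, and adjusted p = 0.916 with an estimated correlation). Besides Cish, Socs3 rose by 4.39, the kinase gene Pim1 by 3.28 and Stat5a by 2.27. Ptpn6 had -0.50 (adjusted p = 0.146, and 0.0407 with the block).

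Pattern recognition receptors and adaptors were mixed: 7 of 36 rose and Card9 fell (12 and 5 adjusted over the list alone, 14 and 5 with the replicate block), with a median of 0.18 and slide medians of 0.24 and 0.11 (camera adjusted p = 0.00846, and adjusted p = 0.973 with an estimated correlation). Nod2, a sensor of bacterial peptidoglycan, rose by 3.16, the formyl peptide receptor gene Fpr1, above background on 1 of 2 control arrays, by 2.79, Tlr1 by 1.69 and the C-type lectin gene Clec4e by 1.56. Of 18 genes for nitric oxide, prostaglandin and itaconate enzymes 7 rose and none fell (7 and 2 over the list alone), with a median of 0.14 and slide medians of 0.13 and 0.16 (camera adjusted p = 0.0116, and adjusted p = 0.973 with an estimated correlation). Acod1, whose product makes itaconate, rose by 4.77 ± 0.16. Cybb, a subunit of the phagocyte oxidase, rose by 1.57, while its partner Cyba had -0.25 (adjusted p = 0.390). Antigen presentation and co-stimulation genes rose in 6 of 25 cases and fell in none (8 and 0 over the list alone), with a median of 0.06 and slide medians of 0.08 and 0.07 (camera adjusted p = 0.00846, and adjusted p = 0.973 with an estimated correlation). Among the risers, besides Cd40, were the genes of the T cell ligands Cd274 at 3.61 and Icosl at 3.60, and Cd83 at 2.81, while Psme2, a proteasome activator subunit, had 0.06 (adjusted p = 0.814).

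Inflammasome and cell death genes rose in 9 of 28 cases and fell in none (13 and 1 adjusted over the list alone, 13 and 2 with the block), with a median of 0.44 and slide medians of 0.44 and 0.48 (camera adjusted p = 5.67e-05, and adjusted p = 0.973 with an estimated correlation). The TNF receptor gene Tnfrsf1b rose by 4.53, Fas by 2.82, the inflammasome sensor Nlrp3 by 2.76 and the survival gene Bcl2a1d by 1.79. Mcl1 had 0.67 (adjusted p = 0.0739, and 0.0372 with the block). Proteases and matrix genes rose in 11 of 24 cases and fell in 2, Plau and Mmp19 (15 and 3 over the list alone), with a median of 1.05 and slide medians of 0.98 and 1.11 (camera adjusted p = 2.16e-07, and adjusted p = 0.587 with an estimated correlation). Saa3, an acute-phase protein gene, rose by 5.11, the protease inhibitor gene Timp1 by 3.92 and the gelatinase gene Mmp9 by 2.91. Adamts4 and Thbs1, not well above background on either control array, were at least 4.56-fold and 2.67-fold higher, but had 0.50 (adjusted p = 0.0617) and 0.18 (adjusted p = 0.410) after normexp correction.

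**Figure D3:**
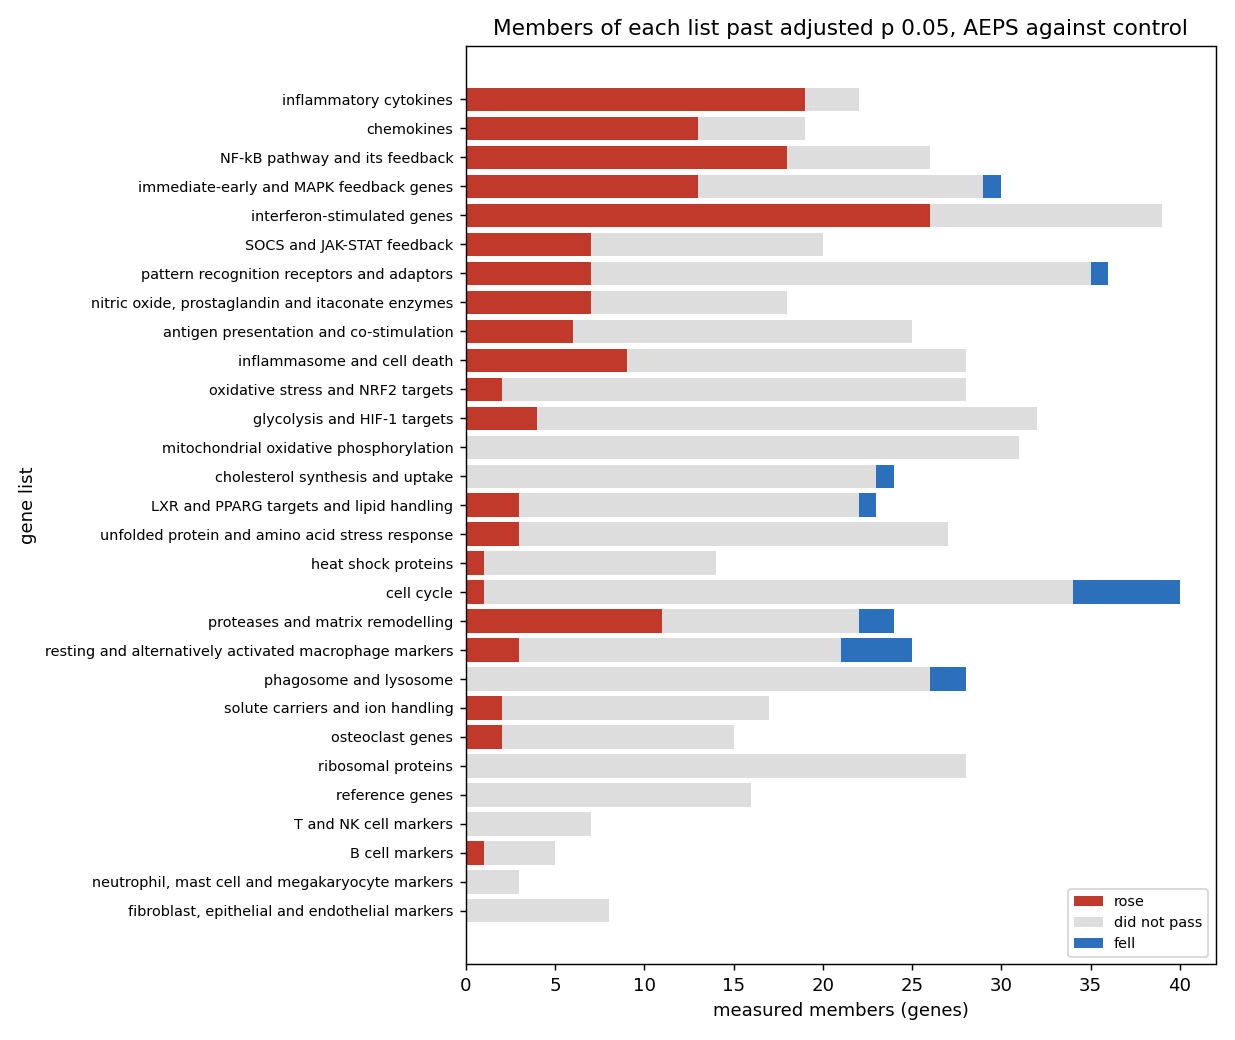
Number of measured members (x axis, genes) of each of the 29 lists fixed in advance (y axis) that rose (red), fell (blue) or did not pass an adjusted p of 0.05 (grey). Interferon-stimulated genes hold 26 risers of 39 measured and cytokines 19 of 22, while the cell cycle list holds 6 that fell of 40.

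In the unfolded protein and amino acid stress list 3 of 27 rose (7 up and 2 down adjusted over the list alone, 9 and 5 with the replicate block), with a median of 0.29 and slide medians of 0.35 and 0.24 (camera adjusted p = 0.00460, and adjusted p = 0.973 with an estimated correlation). These were Cth at 1.71, Herpud1 at 1.40 and Chac1 at 1.13. Atf4 had 0.52 (adjusted p = 0.110, and 0.0434 with the block). Solute carriers rose in 2 of 17 cases (6 over the list alone, 7 with the block), the copper carrier gene Slc31a2 by 2.45 and the phosphate carrier gene Slc20a1 by 1.53, with a list median of 0.31 and slide medians of 0.27 and 0.30 (camera adjusted p = 0.000279, and adjusted p = 0.973 with an estimated correlation). Without the second AEPS array the unfolded protein list no longer passed camera (adjusted p = 0.109). Among NRF2 targets Slc7a11, the cystine carrier gene, above background on 1 of 2 control arrays, rose by 3.29 and Nfe2l2 by 1.33, 2 of 28 (6 and 1 over the list alone, 6 and 6 with the block). Of 32 glycolysis and HIF-1 genes 4 rose (7 and 3 over the list alone, 9 and 5 with the block): Ero1a by 1.64, Vegfa by 1.44, Pfkfb3 by 1.21 and Hif1a by 1.09. Pfkfb3 had 0.60 and did not pass with the mean of its probes (adjusted p = 0.110). The median of the NRF2 list was -0.17 (slides -0.16 and -0.10) and that of the glycolysis list -0.07 (slides -0.04 and -0.10), while both means were 0.07 and both medians lay above 0 with quantile normalization, spike-in scaling and in the authors' table. Neither passed camera (adjusted p = 0.773 and 0.415), though the glycolysis list did in 1 of 18 alternatives, normexp correction (adjusted p = 0.0195, others up to 0.837, and adjusted p = 0.731 with an estimated correlation). Heat shock proteins rose in 1 of 14 cases, Dnajb4 at 1.13 (1 over the list alone, 7 up and 1 down with the block), with a list median of 0.30 and slide medians of 0.31 and 0.30. Camera gave an adjusted p of 0.0640, and 0.00565 to 0.290 in 18 alternatives. The list passed in 8 of them, among them without the second control array (0.0194) and without the first AEPS array (0.0119), but in none with an estimated correlation (lowest adjusted p = 0.422). Dnajb4 had 0.39 and did not pass after normexp correction (adjusted p = 0.141).

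In lipid handling, the cholesterol exporter genes Abca1 and Abcg1 went opposite ways, at 2.55 ± 0.13 (adjusted p = 0.0122) and -2.25 ± 0.14 (adjusted p = 0.0146). Ch25h, encoding cholesterol 25-hydroxylase, was at least 7.75-fold higher and Fabp4 rose by 1.62, so 3 of 23 members of that list rose and 1 fell (4 and 1 adjusted over the list alone, 5 and 4 with the replicate block). Its median was -0.01, with slide medians of 0.05 and -0.02, and its mean 0.24 (camera adjusted p = 0.274, direction up). Of 24 cholesterol synthesis genes only Dhcr7 passed, at -1.25 (5 up and 3 down over the list alone, 7 and 4 with the block). The median was 0.09 on both slides, and camera gave an adjusted p of 0.175, and 0.0133 to 0.592 in 18 alternatives. It passed in 3 of them, among them without the first AEPS array (0.0495), but in none with an estimated correlation (lowest adjusted p = 0.493). Dhcr7 lost its call with spike-in scaling (-0.59, adjusted p = 0.0704). None of 31 oxidative phosphorylation genes passed limma's adjusted test (0 over the list alone, 6 at an unadjusted p under 0.05, 1 up and 4 down with the block). Their median was -0.15, with slide medians of -0.14 and -0.16, and above 0 with spike-in scaling (camera adjusted p = 0.671).

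Cell cycle genes fell in 6 of 40 cases and rose in 1 (13 down and 3 up adjusted over the list alone, 16 and 4 with the replicate block). The transcription factor gene E2f2 had -2.08 ± 0.15, the G1 cyclin gene Ccne1 -1.41 and the replication licensing gene Cdc6 -1.41, while Ccnd2 rose by 1.96 but had 0.66 and did not pass after normexp correction (adjusted p = 0.0630). The list's median was -0.26, with slide medians of -0.24 and -0.28 (camera adjusted p = 0.111, and 0.0146 to 0.727 in 18 alternatives). It passed in 3 of them, among them the authors' table (0.0146) and without the second AEPS array (0.0167), but in none with an estimated correlation (lowest adjusted p = 0.357). The median turned to 0.39 with spike-in scaling, under which Cdc6 no longer passed (-0.75, adjusted p = 0.0733). Markers of resting or alternatively activated macrophages went both ways, 3 up and 4 down of 25 (3 and 5 over the list alone, 5 and 6 with the block). Irf4 and Cebpd rose by 2.36 and 2.33, and Axl by 1.80. The list's median was -0.07, with 0.03 and -0.08 on the slides, and above 0 with quantile normalization, spike-in scaling and in the authors' table (camera adjusted p = 0.840, direction up). Of 28 phagosome and lysosome genes 2 fell (2 over the list alone, 5 up and 5 down with the block), Tfeb, a regulator of lysosomal genes, at -1.81 and Psap at -0.95; the median was -0.13, with slide medians of -0.08 and -0.10, and above 0 with spike-in scaling (camera adjusted p = 0.907, direction up). Psap no longer passed when arrays were scaled to spike-ins (-0.29, adjusted p = 0.301) or to the median (-0.93, adjusted p = 0.0565). Of 15 osteoclast genes Mmp9 and Jdp2 (1.51) rose (4 up and 1 down over the list alone, 5 and 1 with the block), with a median of 0.03 and a camera adjusted p of 0.0750, and 0.00565 to 0.191 in 18 alternatives. The list passed in 5 of them, among them without the second control array (0.0266) and without the first AEPS array (0.0132), but in none with an estimated correlation (lowest adjusted p = 0.419).

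Ribosomal protein genes had a median of -0.35, with slide medians of -0.24 and -0.45, and no member of 28 passed limma's adjusted test (0 adjusted over the list alone, 4 at an unadjusted p under 0.05, 5 lower with the replicate block). Camera gave an adjusted p of 0.0597, and 0.00206 to 0.640 in 18 alternatives. The list passed in 5 of them, among them the block (0.0329), without the first control array (0.00206) and without the second AEPS array (0.00965), but in none with an estimated correlation (lowest adjusted p = 0.286). The median was 0.07 in the authors' table, 0.05 after quantile normalization and 0.31 with spike-in scaling. Of 16 reference genes none passed (0 over the list alone, 4 unadjusted, 1 up and 1 down with the block). Their median was -0.16, with slide medians of -0.11 and -0.17, and was 0.04 in the authors' table and 0.50 with spike-in scaling (camera adjusted p = 0.788).

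Few markers of other cell types were measured, as a background check. Of 7 T and NK cell markers none passed (0 adjusted over the list alone, 3 unadjusted, 2 lower with the block and 4 lower in the authors' table). Their median was -0.55, with slide medians of -0.43 and -0.69, and 0.11 with spike-in scaling, where camera's direction was still down (camera adjusted p = 0.0597, and 0.0119 to 0.162 in 18 alternatives). The list passed in 8 of them, among them without the second control array (0.0384) and without the first AEPS array (0.0119), but in none with an estimated correlation (lowest adjusted p = 0.286). Cd4, the brightest of them, had -0.55 (adjusted p = 0.158, and 0.0479 with the block). Of 5 B cell markers Cd79b, a B cell receptor subunit, rose by 2.59 ± 0.14 (adjusted p = 0.0125; 1 over the list alone), while its partner Cd79a had -0.25 (adjusted p = 0.588). The list's median was -0.39, with slide medians of -0.13 and -0.55 and 0.27 with spike-in scaling, and its mean 0.05 (camera adjusted p = 0.946). None of 3 markers of neutrophils, mast cells and megakaryocytes passed (0 over the list alone, 1 unadjusted), with a median of 0.12, slide medians of 0.16 and -0.31 and a mean of -0.04 (camera adjusted p = 0.855). None of 8 markers of fibroblasts, epithelium and endothelium passed (1 lower over the list alone, 3 unadjusted, 2 lower with the block), with a median of -0.44, slide medians of -0.27 and -0.61, and 0.22 with spike-in scaling (camera adjusted p = 0.788).

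Outside the lists, the largest rises measured on all arrays included Hdc, encoding the histamine-forming decarboxylase, at 5.47 ± 0.17 and Mab21l3 at 4.72 ± 0.21. Marcks was at least 41.8-fold higher than a control level not well above background. In all, 75 genes past the test rose from background and 32 fell to it. Among the latter Fcnb was at least 5.93-fold lower, Gm13498 at least 5.35-fold, Fbp2 at least 4.31-fold, Scara5 at least 4.11-fold and D930027P08Rik at least 4.07-fold. Scara5 did not pass with spike-in scaling (-1.38, adjusted p = 0.0799), nor D930027P08Rik with quantile normalization (-1.78, adjusted p = 0.0988). These log2 changes are smaller than the bounds, which hold for the 75th percentile scaling only. Further falls among genes measured on all arrays were the Polycomb gene Cbx2 at -2.88, Mxd3, a MYC-network repressor, at -2.86, Abhd15 at -2.76, Prtg and Shb at -2.65 each, Pwwp2b at -2.59 and Calhm2 at -2.54.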

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

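The spike-in scaling, the omission of probes bright on 1 array alone, the block and leave-outs within the authors' table, and the estimated correlation in the table and in other alternatives were chosen after seeing the data. Of 1285 genes past the threshold (775 higher, 510 lower, 1075 with 2-fold), median scaling, keeping spots set aside by the scanner, the filter on every array, the mean of a gene's probes, an unadjusted p with 2-fold and the omission of bright probes gave totals from 1131 to 1591. Other totals, with higher and lower genes, were 4964 (2442 and 2522) with the replicate block, 2931 (1470 and 1461) with normexp, 2096 (1246 and 850) with quantile normalization, 3838 (2099 and 1739) with the 75th percentile over probes above background, 6082 (3178 and 2904) in the authors' table, 3531 (1927 and 1604) with trend and robust eBayes, and 4396 (4260 and 136, 3145 with 2-fold) with spike-in scaling. Counting the identical files separately gave 7782 (3712 and 4070), by construction with a spread of 0 between copies. Testing against 1.5-fold gave 271 (210 and 61, all with 2-fold). The filter on at least 1 array gave 81 (77 and 4, all with 2-fold). No filter gave 0 in each count (4300 at an unadjusted p under 0.05), as did a plain test of each gene without pooled variance (4453 unadjusted), while limma with the filter gave 5328 unadjusted. Leaving out each array gave 7 to 514 genes, 7 to 334 higher, 0 to 180 lower (0 of 1545 unadjusted without the first control array) and 7 to 514 with 2-fold; the lone array left in a group is then assumed to vary like the others. In the authors' table, the replicate block gave 8320 genes, and leave-outs gave 4043 (without AEPS replicate 2) to 5234, with 2089 (without AEPS replicate 2) to 2830 higher and 1862 (without control replicate 2) to 2566 lower. Apart from the construction named, the cause was not tested. Of 13 lists past camera, 0 passed with an estimated correlation and 7 with fry (not antigen presentation and inflammasome, adjusted p = 0.0611 each, nitric oxide enzymes, 0.0684, solute carriers, 0.0761, pattern recognition, 0.104, and unfolded protein, 0.154); 0 of the table's 16 passed with an estimated correlation, and no list passed with one in any of 18 alternatives (lowest adjusted p = 0.134); other alternatives gave 13 to 17 lists, and the 13 passed in each of them except without AEPS replicate 3 (12). With so few arrays per group an estimated correlation leaves camera little power, so lists failing with it decide little. The estimates for the 13 lists ran from 0.15 to 0.71, against the preset 0.01. Camera's preset p-values may therefore be far too small. The mean correlation between arrays within groups, 0.992, was 0.993 with quantile normalization and in the table. Of 101 named genes past the threshold, 97 passed with normexp and with spike-in scaling, 99 with quantile normalization, 101 with the block and in the table, 71 against 1.5-fold, 40 with the filter on at least 1 array, and 6, 23, 88 and 76 without the first and second control and AEPS arrays. Of the 101 log2 changes, 28 shrank by over 1.5 times with normexp and 3 with the mean of probes, and with spike-in scaling 5 shrank and 4 grew by as much. Of 32 named genes that did not pass, 11 passed with the block, 13 in the table, 10 with the 75th percentile over probes above background, 9 with spike-in scaling, 7 with trend and robust eBayes, 6 with normexp, 5 with quantile normalization and 19 with the identical files counted separately. Besides these, the ribosomal list and the counts given, the block changed no other call among named genes and lists. No named gene or list past the threshold changed direction in any alternative run. Signal over background limits the dim genes. The 75th percentile was 8.71 and 11.5 times the median local background on the control arrays, and 12.8 and 18.1 times on the AEPS arrays. Relative to the 75th percentile, local background was thus lower on the AEPS array of each slide. Whether this lowered dim genes with AEPS, such as markers of other cell types or genes falling to background, was not tested.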

Other observations

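The tests on histones, replication genes, spike-ins, bright genes and probes bright on 1 array were chosen after their results had been seen at least in part; the splits of the samples were planned. Histone genes were in no list. Of 56 measured, 16 fell and none rose by limma (38 fell and 2 rose with the replicate block), with a median log2 change of -0.78, and -0.72 and -0.87 on slides 1 and 2. The linker histone gene H1f4 had -1.75 (adjusted p = 0.0239), H2bc18 -1.66 (adjusted p = 0.0232) and H3c11 -1.48 (adjusted p = 0.0328), all picked for their size. In the authors' table the median was -0.57, with 37 lower and 2 higher, and with spike-in scaling it was -0.12.

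The signal level of histone probes is argued against as the cause: the median lay at percentile 0 of 10000 lists matched on signal, whose central range was -0.26 to 0.02. Probes that nearly match one another (90% of bases, overlap of at least 40) and count as separate genes are argued against as the whole cause. Merging 10 such genes left 49 values with a median of -0.77, again at percentile 0. Probes were not compared with transcripts, so signal shared between histone copies through other probes is not excluded. The 42 replication-dependent genes, whose transcripts are made mainly in S phase, had a median of -0.83 with 16 falls and 0 rises (34 and 0 with the block, 33 and 0 in the authors' table), against -0.23 with 0 of either for 10 replacement genes (3 falls and 2 rises both with the block and in the table; exact two-sided Wilcoxon p = 0.00429). Merging near-identical probes and leaving out the pair H2ac20 and H2aj, which join both classes, gave 35 against 9 values (exact Wilcoxon p = 0.00385). The 9 include H4f16 at -1.22 (limma adjusted p = 0.0724) although its class is unsure (exact Wilcoxon p = 0.000873 without it). Histone genes are not independent replicates, so the Wilcoxon p-values and the percentiles compare genes and do not measure spread between samples. Whether fewer cells were in S phase stays open, as do other causes of lower histone mRNA: 10 replication genes of the cell cycle list had a median of -0.22, at percentile 17.2 of matched lists, with 2 falls (Mcm5 and Cdc6), and with spike-in scaling the medians of these and the 2 histone classes were 0.43, -0.17 and 0.43.

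Scaling leaves a second pattern. The log2 changes of the 738 brightest genes differed from those of 2950 genes of middle signal by -0.27 (-0.24 and -0.29 on the slides), and in the authors' table by -0.03. Signal compression at the top of the range stays open: on the array of lower raw signal in each group the log2 signal of the brightest genes relative to middle genes was higher by a mean of 0.0882 (0.08 for controls and 0.10 for AEPS), against 0.20 and 0.10 that compression would need. Spike-in probes cannot test it, as their raw log2 signal differed by only -0.10 and 0.07 between groups. The 8 spike-in probes above background had a mean of -0.66 relative to the 75th percentile (-0.62 and -0.69). More labelled RNA per spike-in and more RNA per cell cannot be told apart, because the amounts added are not given in the sources used here.

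Apart from scaling, there were 1056 probes more than 8-fold brighter on 1 array than on each of the others, 492 of them on the first control array. Of all 1056 probes 87.3% had another within 2 rows and 2 columns, against at most 17.1% in 1000 random placements, consistent with local blemishes. RNA of another cell type in the first control sample is argued against for most of its probes, since 94.5% of them had such a neighbour, against at most 24.6% in random placements. The 75 probes of markers of other cell types did not lie together in the layout (2.67% with another of them that near, and a median of 2.67% for random probes). Over all 4 arrays 17 tested genes had such a probe, 7 of them on the first control array, and without these probes 1314 genes passed.

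For the authors' table, the 10 splits of 6 samples into 3 and 3 are too few for a share under 0.05. The real split gave 6082 genes and was the 1 split with as many, the highest other giving 0. It gave 16 lists, the highest other giving 10 (control replicate 1 with AEPS replicates 2 and 3). The 3 other splits that part every replicate pair gave 0 genes each and 7, 7 and 10 lists. Every split but the real one has AEPS and control samples on both sides, which puts the difference between treatments into the spread within groups. The other splits therefore give no chance level for either count.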
